A study of Mus musculus with 43 samples.

How the data were processed

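RNA was measured in mononuclear phagocytes sorted from the lungs of newborn C57BL/6 mice that had been kept in air (normoxia) or in a fraction of inspired oxygen of 0.9 (hyperoxia) for 1.5 days. Per the labels, the sorts gave 4 populations: dendritic cells (DC, high MHC class II and CD11c), alveolar macrophages (AM, high Siglec-F and CD11c), Ly6Chi mononuclear cells (high Ly6C, low CD11c) and Ly6Clo mononuclear cells (low Ly6C, high CD11c). The 43 libraries come from 3 litters, named 93, 100 and 108, and every litter holds libraries of both oxygen conditions in every population. The litter was therefore used as the block. Replicate numbers were given in the order of the deposit and were not used to pair libraries. The labels do not tie libraries to single pups and give no sex. Y-linked expression was alike across the populations for each number within an oxygen condition (5.82 to 6.06 in normoxia replicate 1 and −0.73 to 0.14 in normoxia replicate 5, log2 CPM), as it would be if these libraries came from 1 pup. Comparisons between populations take no account of this. P-values of single genes measure the spread between libraries.

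The deposited table holds whole-number counts per Ensembl gene that carry no normalization. Per the submitters' processing notes, TopHat, HTSeq 0.4.1, FastQC, Picard and SAMtools were used with mouse genome build NCBIM37. The notes give neither the role nor the order of these tools, nor the annotation release. Libraries were made with the SMART-Seq v4 and Nextera XT kits, which carry no molecular identifiers. The table has 37991 genes, of which 32919 were given a symbol by matching their Ensembl identifier to the GENCODE M21 annotation of build GRCm38. That annotation is of a later build, so it was used for gene names and exonic lengths only and no positions are given. Genes without a symbol hold 0.828% of all counts and were tested and counted but not named. At least 1 count was found for 23846 genes.

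Counts look limited for the most abundant transcripts. The highest count of any gene in any library is 4012, the highest count per exonic base is 1.73, and 0 genes reach 2 counts per exonic base in any library. The count of Tmsb4x, which encodes an abundant actin-binding peptide, ranged from 977 to 1219, or 1.25-fold, while library totals ranged 4.36-fold. Reads at the same position may thus have been collapsed before counting, and differences in the most abundant transcripts can be compressed. An alternative that corrects counts for such a limit was therefore added.

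Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1, with DESeq2 1.42.0 as an alternative, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9. For each comparison genes were kept by edgeR filterByExpr with a minimum count of 10 and a minimum total of 15. Libraries were scaled by the trimmed mean of M values (TMM), and dispersions and quasi-likelihood fits were robust. Litter was an additive term. Quasi-likelihood F tests were adjusted by the method of Benjamini and Hochberg over all genes tested in the comparison, and a gene was called at an adjusted p under 0.05. Fold changes are log2 with their standard error (SE), computed with a prior count of 0.125. Levels are TMM-scaled counts in a library of 1000000 (CPM), with the standard deviation (SD) between libraries of a group. Means of log2 CPM used a prior count of 1.

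The hyperoxia comparisons were fitted within each population, with 6 normoxic libraries (5 for Ly6Clo) against 5 hyperoxic ones. A fit of all 43 libraries tested whether the hyperoxia effect differs between the 4 populations, and a fit of the Ly6Chi and Ly6Clo libraries tested whether it differs between those populations. Ly6Chi was compared with Ly6Clo within normoxia and within hyperoxia, and each normoxic population was compared with the mean of the other 3. The 28 gene lists cover p53 targets, NRF2 antioxidant genes, metallothionein and zinc genes, cell cycle, type I interferon, interferon gamma, MHC class II, inflammatory NF-kB, hypoxia (HIF targets), alternative activation, tissue remodelling, ER stress and ATF4, immediate early genes of tissue dissociation, cholesterol synthesis and oxidative phosphorylation. They also hold markers of alveolar macrophages, dendritic cells, classical monocytes, non-classical monocytes, interstitial macrophages, neutrophils, epithelium, endothelium, mesenchyme, T and NK cells, B cells, erythroid cells, and of granulocytes, mast cells and platelets. Each list was tested against all other genes by limma camera with a preset inter-gene correlation of 0.01, adjusted over 28 lists and 4 populations together, or over 28 lists for the difference between Ly6Chi and Ly6Clo. The same test was repeated with an estimated correlation. Camera compares genes with genes, so its p-values with the preset correlation largely measure the spread across genes and not between libraries. The estimated correlation was 0.49 for cell cycle genes and 0.65 for endothelial markers in the difference between Ly6Chi and Ly6Clo. Rotation tests (fry) asked whether the members of a list moved together in the same direction, and their mixed form whether members moved in any direction. A camera result from a list with 1 measured gene says no more than that gene.

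The groups, tests, lists, most other settings and the rule for naming genes were fixed before the data were examined. The rule names, for each comparison, up to 12 genes per direction with the largest fold change among those called, with at least 10 CPM in a group and the same sign in all 3 litters, or the 5 with the smallest p where none passed. It further names up to 4 members of each list, those with the smallest p, and in every population the genes of the sort markers and of interferon gamma and its receptor. Any other gene named was chosen after its values were seen, and this is said where it occurs. Some genes that the rule names are not reported here.

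Other settings left out the litter term, the filter, each litter or each library, required at least 10 CPM, used DESeq2 size factors in edgeR or DESeq2 itself, and used limma voom with quality weights. They also added the number of detected genes or the expression of 4 Y-linked genes as a covariate, and fitted all 43 libraries together. Settings added after the data were seen thinned all libraries to the smallest total, corrected counts for saturation, and left out libraries under 1000000 counts. The last was not run in DC and Ly6Chi, which have no such library. For each count of calls the libraries of the comparison were split at random into groups of the same sizes, up to 100 times with the real split included, and litter stayed in the fit. For the differences between populations, the oxygen labels were split anew within each population, which does not keep libraries of a possible shared pup together.

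The tests were tested on simulated data with 200 changed genes. In the hyperoxia comparisons 2-fold changes were recovered for 66.7% of genes in DC, 37.4% in AM, 52.0% in Ly6Chi and 36.1% in Ly6Clo, and 4-fold changes for 94.9%, 85.0%, 85.7% and 93.9%. False calls were 5 of 169, 7 of 132, 5 of 143 and 6 of 137. For the difference between the hyperoxia effects in Ly6Chi and Ly6Clo, 17.9% of 2-fold and 67.7% of 4-fold changes were recovered, so small differences can be missed. A shift of 0.5 on the log2 scale in the NRF2 list was recovered in all 5 list comparisons with both correlations. Simulated genes were drawn independently of each other and without a litter effect. The recovery thus says nothing of lists whose members move together.

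Depth per library was 551960 to 2403861 counts, with a median of 1574479, and 13306 to 16617 genes had at least 1 count. Where a gene had 0 counts in a whole group, folds are lower bounds against a floor of 3 counts over the group. Floors cover counting error only. All 43 count columns were used and 0 were left out. Within a population, hyperoxic and normoxic libraries of the same litter had a mean correlation of 0.14 to 0.18 across genes, after subtracting group means, against −0.08 to −0.06 for those of different litters.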

Results

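The 43 libraries form 8 groups: normoxia and hyperoxia in each of 4 sorted populations. DC, AM and Ly6Chi had 6 normoxic libraries each and Ly6Clo had 5, and every hyperoxic group had 5. Each normoxic group held 2 libraries of each litter, except Ly6Clo with 1 of litter 108. Each hyperoxic group held 2 libraries of litter 93, 1 of litter 100 (replicate 3 in every population) and 2 of litter 108. The mean total (± SD) was 1802310 ± 431024 counts in DC normoxia (1152853 to 2403861) and 1785550 ± 415256 in DC hyperoxia (1309747 to 2373600). It was 1234960 ± 375641 in AM normoxia (570769 to 1701878) and 986411 ± 411523 in AM hyperoxia (551960 to 1636916). Ly6Chi had 2016350 ± 343540 in normoxia (1525352 to 2393286) and 1806910 ± 510712 in hyperoxia (1026528 to 2298828). Ly6Clo had 1422340 ± 240952 in normoxia (1177993 to 1746742) and 1397240 ± 535015 in hyperoxia (647844 to 1963284).

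Comparing each normoxic population with the mean of the other 3 asks what the sorts held. Siglecf, the gene of the Siglec-F sort marker, was at 129.7 ± 33.6 CPM (SD) in normoxic AM (n = 6) and at 2.96 to 19.6 CPM on average in the groups of the other populations. H2-Ab1, a chain of MHC class II, was at 1190 ± 230 CPM in normoxic DC against 94.4 ± 34.5 CPM in Ly6Chi and 138 ± 43.5 CPM in Ly6Clo. Ly6c2 was at 413 ± 65.5 CPM in normoxic Ly6Chi, 18.9 ± 6.09 CPM in Ly6Clo, 138 ± 26.4 CPM in DC and 22.4 ± 14.0 CPM in AM. Ly6c1 was closer between populations, at 61.4 ± 22.2 CPM in Ly6Chi, 20.5 ± 9.04 CPM in Ly6Clo, 22.0 ± 14.4 CPM in DC and 64.4 ± 39.0 CPM in AM. Itgax, which encodes CD11c, was at 207 ± 39.7 CPM in AM, 168.5 ± 17.3 CPM in Ly6Clo, 159 ± 22.4 CPM in DC and 7.97 ± 4.51 CPM in Ly6Chi.

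DC were higher in all 19 dendritic cell markers (median log2 fold change 4.81) and in 9 of 9 MHC class II genes (2.90), and lower in 18 of 19 alveolar macrophage markers. They were also higher in all 6 measured B cell markers (2.95) and in 11 of 17 interstitial macrophage markers. AM were higher in 18 of 19 alveolar macrophage markers (2.52) and in 13 of 17 cholesterol synthesis genes, and lower in 25 of 26 type I interferon genes (−3.46), 18 of 22 interferon gamma genes and 13 of 16 classical monocyte markers. Ly6Chi were higher in 16 of 16 classical monocyte markers (2.50), 15 of 16 neutrophil markers, 25 of 26 type I interferon genes (2.76) and 11 of 15 non-classical monocyte markers. Ly6Clo were higher in 13 of 19 alveolar macrophage markers (1.38) and 13 of 17 interstitial macrophage markers (1.53), and lower in 25 of 36 cell cycle genes (−1.05). Surfactant protein C (Sftpc), an epithelial transcript, was found in every group at a mean of 307 to 899 CPM. Adjusted over the list alone, the counts were 14 of 17 cholesterol synthesis genes in AM, 15 of 19 alveolar macrophage markers, 14 of 17 interstitial macrophage markers and 33 of 36 cell cycle genes in Ly6Clo.

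Of 11979 genes tested, 4049 differed in DC (2264 higher, 1785 lower), 6059 in AM (2833 higher, 3226 lower), 5220 in Ly6Chi (2893 higher, 2327 lower) and 1440 in Ly6Clo (1020 higher, 420 lower). The 4 comparisons share libraries.

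Hyperoxia raised 11 genes in AM, and 0 were called lower, of 9986 tested (5 hyperoxic against 6 normoxic libraries). Clec4d, a C-type lectin receptor of myeloid cells, rose from 58.2 ± 17.8 to 221 ± 93.0 CPM (SD), a log2 fold change of 1.97 ± 0.21 (SE, adjusted p = 0.000532). The p53 target Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, rose from 110.5 ± 26.6 to 275 ± 73.9 CPM (1.37 ± 0.17, adjusted p = 0.00184). The p53 targets Zmat3 (1.72 ± 0.28, adjusted p = 0.0176) and Ccng1 (0.85 ± 0.14, adjusted p = 0.0165) rose too. Blvrb, a biliverdin reductase of haem breakdown, rose from 153 ± 32.3 to 312 ± 39.0 CPM (0.98 ± 0.13, adjusted p = 0.00198). Slc11a1, a metal transporter of phagosomes, rose 7.06-fold (2.82 ± 0.46, adjusted p = 0.0234), and Itgam, which encodes CD11b, rose 3.25-fold (1.70 ± 0.28, adjusted p = 0.0186).

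Also called in AM were Rnf128, an E3 ubiquitin ligase, which rose 3.90-fold (1.96 ± 0.26, adjusted p = 0.00198), and Esd, an S-formylglutathione hydrolase, which rose 1.81-fold (0.86 ± 0.11, adjusted p = 0.00198). The last were Creg1, a secreted glycoprotein, which rose 1.71-fold (0.77 ± 0.11, adjusted p = 0.00486), and Dst, a cytoskeletal linker, which rose 2.05-fold (1.03 ± 0.17, adjusted p = 0.0202). All 11 had the same sign in each of the 3 litters. At an unadjusted p under 0.05 the count was 990, DESeq2 called 111 genes, limma voom 258 and edgeR without the filter on low counts 325, all 11 among them. The count of 11 fell to 0 without litter 93, without libraries under 1000000 counts and with the number of detected genes as a covariate, and to 5 without litter 108. In the fits with 0 calls the log2 fold changes of the 11 genes kept their sign, from 0.74 to 3.17 without litter 93, 0.67 to 3.15 without the small libraries and 0.59 to 2.14 with the covariate. The count was 17 without normoxia replicate 4, 39 without hyperoxia replicate 4, 7 without normoxia replicate 6, and 5 without hyperoxia replicate 3 or without normoxia replicate 5.

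Clec4d, Rnf128, Cdkn1a, Blvrb and Esd stayed called whichever library was left out. Without hyperoxia replicate 3 or normoxia replicate 5 the calls of the other 6 genes ended, with adjusted p up to 0.343 for Dst, 0.295 for Slc11a1 and Zmat3, 0.228 for Itgam, 0.0935 for Ccng1 and 0.0765 for Creg1. Calls also ended without normoxia replicate 6 for Slc11a1 (adjusted p = 0.128), Zmat3, Itgam and Ccng1 (each 0.0847), and without normoxia replicate 1 for Slc11a1 and Dst (each 0.0833). They ended without hyperoxia replicate 2 for Slc11a1 (0.122), Dst (0.0801) and Ccng1 (0.0579), without hyperoxia replicate 5 for Slc11a1 and Dst (each 0.0506), without hyperoxia replicate 1 for Dst (0.0726) and without normoxia replicate 2 for Creg1 (0.0505).

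**Figure D1:**
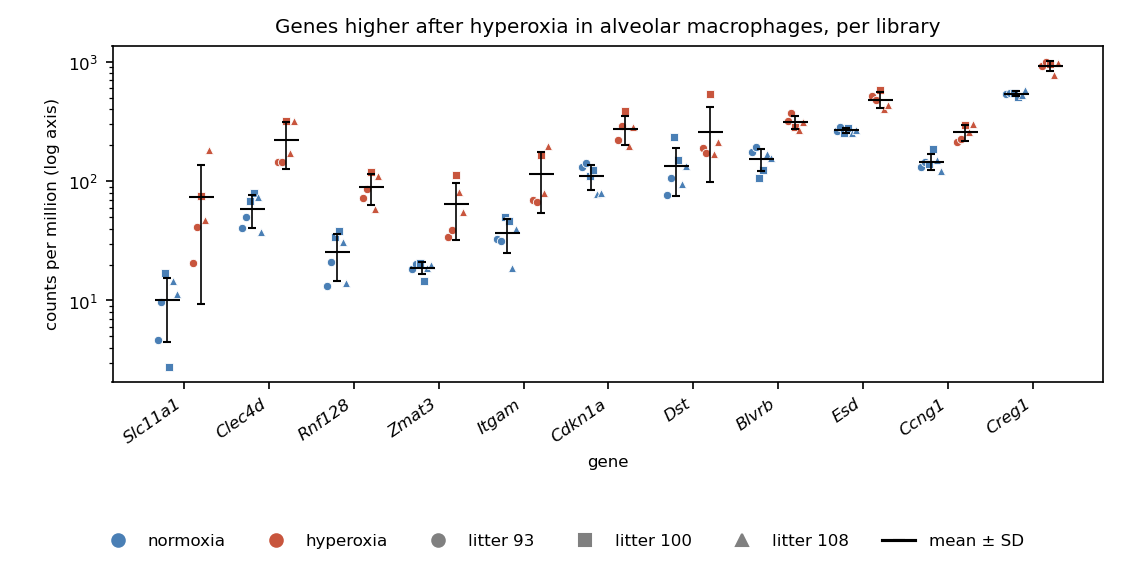
Level of the 11 genes called in AM, in CPM on a log axis, for each normoxic (n = 6) and hyperoxic (n = 5) library, with bars for the mean and SD. Creg1 stands highest, at 542 ± 27.1 CPM in normoxia and 929 ± 90.0 CPM in hyperoxia, and Slc11a1 rises most, from 10.0 ± 5.56 to 73.5 ± 64.1 CPM.

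The NRF2 antioxidant list rose in AM, with a median log2 fold change of 0.54 (camera adjusted p = 1.98e-20, adjusted p = 0.0215 with an estimated correlation). Adjusted over the list alone 16 of 21 measured genes rose, against 1 (Blvrb) over all genes tested. Among them the glutathione synthesis gene Gclm went from 89.5 ± 11.7 to 159.9 ± 18.2 CPM (0.84 ± 0.16). The cystine transporter Slc7a11 went from 67.0 ± 27.5 to 362 ± 216 CPM (2.41 ± 0.38) and haem oxygenase Hmox1 from 162 ± 48.1 to 323 ± 135 CPM (0.84 ± 0.18). The mean log2 CPM of the list was 6.85 to 7.04 in the hyperoxic AM libraries and 6.01 to 6.39 in the normoxic ones.

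The p53 target list rose as well, with a median of 0.36 (camera adjusted p = 3.98e-08, adjusted p = 0.0314 with an estimated correlation). Adjusted over the list alone 8 of 26 genes rose, against 3 over all genes, among them Mdm2, the p53 ubiquitin ligase (94.9 to 179.5 CPM, 0.91 ± 0.18). The single member that fell over the list alone, Ckap2, a mitotic spindle gene named after its value was seen, changed by −1.18 ± 0.33.

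Cell cycle genes were lower in hyperoxic AM, with a median of −0.94 and 0 of 36 higher (camera adjusted p = 1.43e-31, adjusted p = 0.245 with an estimated correlation). Adjusted over the list alone 23 of 36 fell, against 0 over all genes. The replication helicase genes Mcm6 (125 ± 27.2 to 69.7 ± 26.2 CPM, −0.96 ± 0.18) and Mcm2 (−0.95 ± 0.20) and the mitotic genes Tpx2 (−1.08 ± 0.25) and Cdca8 (−1.03 ± 0.24) fell over the list alone. The mean log2 CPM of the list was 6.54 and 6.26 in the hyperoxic libraries of litter 93, within the normoxic range of 5.75 to 6.66, and 4.33 to 5.25 in those of litters 100 and 108.

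Inflammatory NF-kB genes had a median of 0.52 in AM, with all 18 higher (camera adjusted p = 8.79e-09, adjusted p = 0.346 with an estimated correlation). Adjusted over the list alone 6 of 18 rose, against 0 over all genes, among them the interleukin 1 genes Il1rn (0.43 ± 0.12) and Il1a (0.89 ± 0.26), Tnfaip2 (0.70 ± 0.20) and the mitochondrial superoxide dismutase Sod2 (0.51 ± 0.15). Interferon gamma genes had a median of 0.75 (camera adjusted p = 7.57e-07, adjusted p = 0.370 with an estimated correlation). Of these, 2 of 15 rose over the list alone, against 0 over all genes: Cd274, which encodes PD-L1 (0.90 ± 0.18), and the GTPase Igtp (1.89 ± 0.55). Type I interferon genes had a median of 0.73, with 0 of 15 called over the list alone or over all genes (camera adjusted p = 9.18e-05, adjusted p = 0.346 with an estimated correlation).

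Smaller shifts in AM by camera were oxidative phosphorylation (median 0.23, adjusted p = 0.00147, adjusted p = 0.425 with an estimated correlation) and tissue remodelling (0.20, 0.0259, adjusted p = 0.311 with an estimated correlation). A lower list was ER stress and ATF4 (−0.17, 0.0155, adjusted p = 0.346 with an estimated correlation). Over the list alone these held 0 of 28, 1 of 17 (Mmp19, a matrix metalloproteinase, 0.94 ± 0.25) and 1 of 18 (Shmt2, a mitochondrial folate enzyme, −0.99 ± 0.22), and 0 over all genes. Without libraries under 1000000 counts the oxidative phosphorylation median turned to −0.11, with 22 of 28 lower. Interstitial macrophage markers had a median of 0.33 (camera adjusted p = 0.0108, adjusted p = 0.367 with an estimated correlation) with 2 of 14 risen over the list alone, Maf (1.34 ± 0.42) and Pf4 (1.995 ± 0.603), and 0 over all genes. Alveolar macrophage markers were not called (median 0.08, mean −0.03, camera adjusted p = 0.532). Marco, a scavenger receptor (0.65 ± 0.15), and the lipoprotein lipase gene Lpl (0.50 ± 0.14) rose over the list alone. The lipid droplet gene Cidec (−0.87 ± 0.22), the fatty acid binding gene Fabp1 (−1.52 ± 0.40) and Siglecf (−0.63 ± 0.20) fell over the list alone, of 19, with 0 over all genes.

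Markers of other cells moved beside these groups. Epithelial markers had a median of −1.29 in hyperoxic AM, with all 14 lower (camera adjusted p = 9.84e-05, adjusted p = 0.422 with an estimated correlation), and 0 were called over the list alone or over all genes. A single measured B cell marker, Cd79b, had −1.22 ± 0.31 (camera adjusted p = 0.00542, adjusted p = 0.245 with an estimated correlation). A single T and NK cell marker, Il7r, had 1.69 ± 0.46 (0.0259, adjusted p = 0.346 with an estimated correlation). The mean number of genes detected was 13770 ± 558 in hyperoxic AM and 14525 ± 547 in normoxic AM. The NRF2, p53, cell cycle, NF-kB, interferon gamma and epithelial calls held with the preset correlation without each litter and each library. Without hyperoxia replicate 3, the hyperoxic library of litter 100, the medians fell to 0.31 for interferon gamma, 0.23 for NF-kB and 0.44 for type I interferon genes. The epithelial median ranged from −2.19 without hyperoxia replicate 4 to −0.46 without normoxia replicate 1, and was −0.85 without hyperoxia replicate 5.

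**Figure D2:**
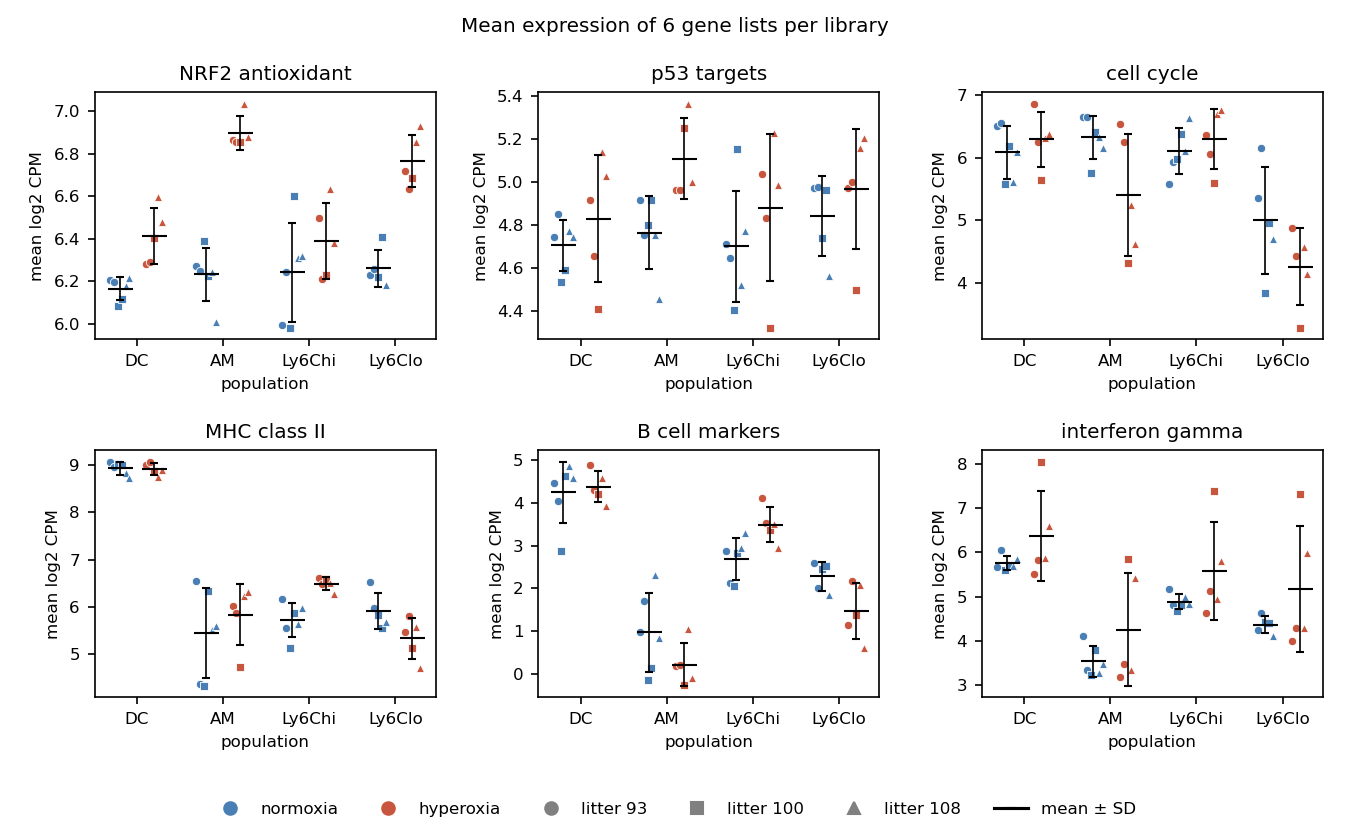
Mean log2 CPM of 6 gene lists in every library, by population and oxygen condition, with shapes for the litter and bars for the mean and SD. The NRF2 list sits at 6.85 to 7.04 in the hyperoxic AM libraries and at 6.01 to 6.39 in the normoxic ones.

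In DC edgeR called 0 genes of 11274 tested (5 hyperoxic against 6 normoxic libraries), with 998 at an unadjusted p under 0.05, 24 called by DESeq2, 1 by limma voom and 369 by edgeR without the filter on low counts. Of the 5 genes with the smallest p, none past the threshold, Lpl, which codes for lipoprotein lipase, led (128 ± 21.1 CPM in normoxia and 233 ± 33.3 CPM in hyperoxia, log2 fold change 0.85 ± 0.13, adjusted p = 0.0624). The others were Adam23 (−1.72 ± 0.34), Ccdc88a (−0.57 ± 0.12), Cdk5rap1 (0.85 ± 0.18) and the transcription factor Tfec (0.81 ± 0.17). Without hyperoxia replicate 4 the count was 23.

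NRF2 antioxidant genes were higher in hyperoxic DC by camera, with a median of 0.21 and 17 of 21 higher (adjusted p = 1.34e-05, adjusted p = 0.0538 with an estimated correlation). Over the list alone 2 of 21 rose, against 0 over all genes: the peroxiredoxin Prdx1 (319.6 to 404 CPM, 0.42 ± 0.11) and Blvrb (109 to 215 CPM, 0.92 ± 0.24). Dendritic cell markers had a median of −0.43, with 2 of 19 higher and 0 called over the list alone or over all genes (camera adjusted p = 1.01e-07, adjusted p = 0.346 with an estimated correlation). The chemokine receptor Ccr7 (−0.75 ± 0.24) and the growth factor receptor Flt3 (−0.47 ± 0.16) were among the members with the smallest p. Igf1, insulin-like growth factor 1, rose over its tissue remodelling list alone from 44.8 ± 16.7 to 91.3 ± 16.3 CPM (0.996 ± 0.215), as did Hgf, hepatocyte growth factor (7.23 to 15.6 CPM, 1.08 ± 0.31). The remodelling list had 2 of 20 risen over the list alone, 0 over all genes and a median of 0.21 (camera adjusted p = 0.00147, adjusted p = 0.346 with an estimated correlation). Without hyperoxia replicate 3 its call ended at a median of 0.15.

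Interferon gamma genes had a median of 0.53 in DC, with 21 of 24 higher and 0 called over the list alone or over all genes (camera adjusted p = 4.72e-06, adjusted p = 0.408 with an estimated correlation). NF-kB genes had a median of 0.46 (0.00784, adjusted p = 0.50 with an estimated correlation). Sod2 (0.62 ± 0.17) and Tnfaip2 (0.94 ± 0.27) rose and Relb (−0.66 ± 0.21) and Traf1 (−0.81 ± 0.25) fell over the list alone, of 23, against 0 over all genes. Without hyperoxia replicate 3, the hyperoxic library of litter 100, both calls ended, at a median of 0.11 for the interferon gamma list and 0.15 for the NF-kB list, and the NF-kB call also ended without normoxia replicate 3 (adjusted p = 0.0536). Ankrd37, a target of the hypoxia-inducible factor, fell over the hypoxia list alone from 11.8 to 4.15 CPM (−1.39 ± 0.34), against 0 genes over all genes, and the hypoxia list itself was not called (median −0.11, camera adjusted p = 0.239).

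Camera also called oxidative phosphorylation (median 0.18, adjusted p = 1.40e-06, adjusted p = 0.370 with an estimated correlation) and cell cycle (0.19, 0.00868, adjusted p = 0.771 with an estimated correlation) as higher in DC. Immediate early genes were called lower (−0.11, 0.0242, adjusted p = 0.393 with an estimated correlation). In these 3 lists 0 members passed over the list alone or over all genes. Among markers of other cells it called neutrophil (0.43, 0.0205, adjusted p = 0.428 with an estimated correlation) and classical monocyte (0.15, 0.0108, adjusted p = 0.346 with an estimated correlation) markers as higher. The same held for alveolar macrophage (0.18, 0.0475, adjusted p = 0.346 with an estimated correlation) and interstitial macrophage markers (0.25, 0.0191, adjusted p = 0.346 with an estimated correlation). It called non-classical monocyte (−0.24, 0.0108, adjusted p = 0.475 with an estimated correlation) and endothelial markers (−0.40, 0.0234, adjusted p = 0.542 with an estimated correlation) as lower. The members past the test over the list alone were S100a8 (0.64 ± 0.15) of 11 neutrophil markers, Mgst1 (0.82 ± 0.22) and Hp (0.46 ± 0.13) of 15 classical monocyte markers and Lpl of 15 alveolar macrophage markers, and 0 over all genes. With the preset correlation the NRF2, dendritic cell and oxidative phosphorylation calls held without each litter and each library, and the other 11 did not. The median of neutrophil markers turned to −0.47 without litter 93 and to −0.09 without normoxia replicate 2, and that of cell cycle genes to −0.0190 without litter 108. The dendritic cell median was −0.27 without hyperoxia replicate 3 and the oxidative phosphorylation median 0.11 without hyperoxia replicate 5.

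In Ly6Chi edgeR called 0 genes of 10844 tested (5 hyperoxic against 6 normoxic libraries), with 591 at an unadjusted p under 0.05, 5 called by DESeq2, 0 by limma voom and 235 by edgeR without the filter on low counts. The smallest p belonged to Ankrd37, at 25.3 ± 6.83 CPM in normoxia and 6.71 ± 0.816 CPM in hyperoxia (log2 fold change −1.80 ± 0.28, adjusted p = 0.258), which passed over the hypoxia list alone. Those that followed included Narf (−1.20 ± 0.22), H2-Ab1 (0.998 ± 0.226) and Rapgef5 (−2.62 ± 0.60), none past the threshold. The hypoxia list as a whole was not called (median −0.10, camera adjusted p = 0.242).

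MHC class II genes rose in hyperoxic Ly6Chi, with a median of 0.75 and 8 of 9 higher (camera adjusted p = 6.59e-09, adjusted p = 0.0440 with an estimated correlation). Over the list alone 5 of 9 rose, against 0 over all genes. The median was 0.39 without normoxia replicate 2 and 0.46 without hyperoxia replicate 4. H2-Ab1 went from 93.7 ± 34.8 to 187 ± 47.4 CPM, H2-Eb1 from 32.3 to 72.3 CPM (1.18 ± 0.30) and H2-Aa from 52.4 to 119.7 CPM (1.18 ± 0.36). The mean log2 CPM of the list was 6.27 to 6.61 in hyperoxic and 5.13 to 6.16 in normoxic Ly6Chi libraries. B cell markers were higher in the same libraries, with a median of 0.99 and 6 of 6 higher (camera adjusted p = 6.66e-07, adjusted p = 0.255 with an estimated correlation). Those that rose over the list alone, against 0 over all genes, included Vpreb3 (2.10 ± 0.57), Cd79a (39.0 to 78.7 CPM, 1.03 ± 0.35) and Ms4a1 (0.95 ± 0.35).

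NF-kB genes had a median of 0.49 in Ly6Chi with 21 of 22 higher (camera adjusted p = 6.66e-07, adjusted p = 0.346 with an estimated correlation). Interferon gamma genes had 0.43 with 18 of 19 higher (3.38e-08, adjusted p = 0.346 with an estimated correlation) and oxidative phosphorylation 0.36 (3.90e-07, adjusted p = 0.346 with an estimated correlation). Cell cycle (0.16, 0.00147, adjusted p = 0.592 with an estimated correlation), p53 targets (0.19, 0.0456, adjusted p = 0.393 with an estimated correlation) and NRF2 genes (0.11, 0.0340, adjusted p = 0.346 with an estimated correlation) were called by camera with the preset correlation. These 6 lists had 0 members over the list alone or over all genes, and Cdkn1a had 0.93 ± 0.28. Endothelial markers had a median of −1.32 (camera adjusted p = 1.46e-08, adjusted p = 0.346 with an estimated correlation). Of these, 3 of 11 fell over the list alone, Sox17 (21.8 to 5.24 CPM, −2.15 ± 0.64), Egfl7 (−1.45 ± 0.46) and Esam (−1.90 ± 0.61), and 0 over all genes. Mesenchymal markers had a median of −0.97 with 5 of 5 lower and 0 called over the list alone or over all genes (0.00168, adjusted p = 0.346 with an estimated correlation). Without hyperoxia replicate 3 the interferon gamma call ended at a median of 0.13 and the NF-kB and oxidative phosphorylation medians fell to 0.15 and 0.09. Only the MHC class II, B cell, endothelial and oxidative phosphorylation calls held without each litter and each library with the preset correlation.

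In Ly6Clo edgeR called 0 genes of 10188 tested (5 hyperoxic against 5 normoxic libraries), with 540 at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma voom. By edgeR it was 1 without hyperoxia replicate 4 and 173 without the filter on low counts. Rnf128, called in AM, had the smallest p here, at 9.99 ± 1.98 CPM in normoxia and 58.5 ± 40.1 CPM in hyperoxia (log2 fold change 2.34 ± 0.36, adjusted p = 0.113). The next were Ano10 (1.06 ± 0.23), the proteoglycan Vcan (1.77 ± 0.39), the kinetochore gene Cenpk (−1.995 ± 0.439) and Gnb4 (−1.87 ± 0.42), none past the threshold.

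NRF2 antioxidant genes rose in hyperoxic Ly6Clo, with a median of 0.33 and 20 of 21 higher (camera adjusted p = 5.16e-09, adjusted p = 0.0314 with an estimated correlation). Over the list alone 2 of 21 rose, against 0 over all genes: thioredoxin reductase Txnrd1 (105 ± 10.4 to 186 ± 58.3 CPM, 0.77 ± 0.20) and Blvrb (188 to 312 CPM, 0.77 ± 0.20). The mean log2 CPM of the list was 6.64 to 6.93 in hyperoxic and 6.18 to 6.41 in normoxic libraries. The p53 list was not called (median 0.02, camera adjusted p = 0.0699), though Cdkn1a rose over that list alone from 148 to 243 CPM (0.79 ± 0.19), the single member of 25 to do so, with 0 over all genes.

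Cell cycle genes had a median of −0.76 in hyperoxic Ly6Clo with 0 of 32 higher (camera adjusted p = 8.41e-18, adjusted p = 0.311 with an estimated correlation). The mitotic genes Kif11 (18.8 to 4.10 CPM, −2.05 ± 0.51) and Ccnb2 (90.4 to 41.6 CPM, −1.28 ± 0.34) fell over the list alone, against 0 over all genes. NF-kB genes had a median of 0.60 (camera adjusted p = 2.08e-10, adjusted p = 0.346 with an estimated correlation). Of these, 5 of 22 rose over the list alone, among them Tnfaip2 (0.78 ± 0.21), Relb (1.21 ± 0.38), Il1rn (0.60 ± 0.19) and Ccrl2 (0.71 ± 0.23), and 0 over all genes. Interferon gamma genes had a median of 0.77 with Cd274 (0.72 ± 0.20) and the peptide transporter Tap2 (0.999 ± 0.307) risen over the list alone, of 17, and 0 over all genes (6.59e-09, adjusted p = 0.346 with an estimated correlation). Type I interferon genes had a median of 0.43 with 0 of 22 called over the list alone or over all genes (0.00543, adjusted p = 0.623 with an estimated correlation), but the median turned to −0.14 without hyperoxia replicate 3 and to −0.17 without litter 100. Without hyperoxia replicate 3 the interferon gamma and NF-kB medians fell to 0.21 and 0.27.

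MHC class II genes were lower in hyperoxic Ly6Clo by camera, with a median of −0.52, 0 of 8 higher and 0 called over the list alone or over all genes (camera adjusted p = 0.000725, adjusted p = 0.370 with an estimated correlation). H2-Ab1 was at 139.7 ± 43.8 CPM in normoxia and 93.2 ± 46.2 CPM in hyperoxia (−0.50 ± 0.25). B cell markers were lower in the same libraries, with a median of −1.13 (0.00286, adjusted p = 0.346 with an estimated correlation). Cd79a (28.5 to 11.5 CPM, −1.44 ± 0.50) and Cd79b (156 to 84.6 CPM, −0.98 ± 0.36) fell over the list alone, of 4, with 0 over all genes. Non-classical monocyte markers had a median of −0.68 (1.61e-06, adjusted p = 0.346 with an estimated correlation) and classical monocyte markers −0.52 (0.0266, adjusted p = 0.393 with an estimated correlation). Their members past the test over the list alone were 0 of 15 and 1 of 13, which was Vcan and rose, with 0 over all genes. Cholesterol synthesis (0.23, 0.0128, adjusted p = 0.346 with an estimated correlation) and oxidative phosphorylation (0.21, 0.00731, adjusted p = 0.542 with an estimated correlation) were called with 0 members over the list alone or over all genes. Without normoxia replicate 5 the MHC class II call ended at a median of −0.34 and the cholesterol synthesis call at 0.16, and without litter 93 the B cell call ended. Oxidative phosphorylation was not called without hyperoxia replicate 2 (0.21) or 3 (−0.00), nor classical monocyte markers without normoxia replicate 1 (−0.39) or 5 (−0.36) or hyperoxia replicate 5 (−0.38). The MHC class II and non-classical monocyte medians were −0.32 and −0.43 without hyperoxia replicate 3, and the latter −0.45 without normoxia replicate 5.

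**Figure D3:**
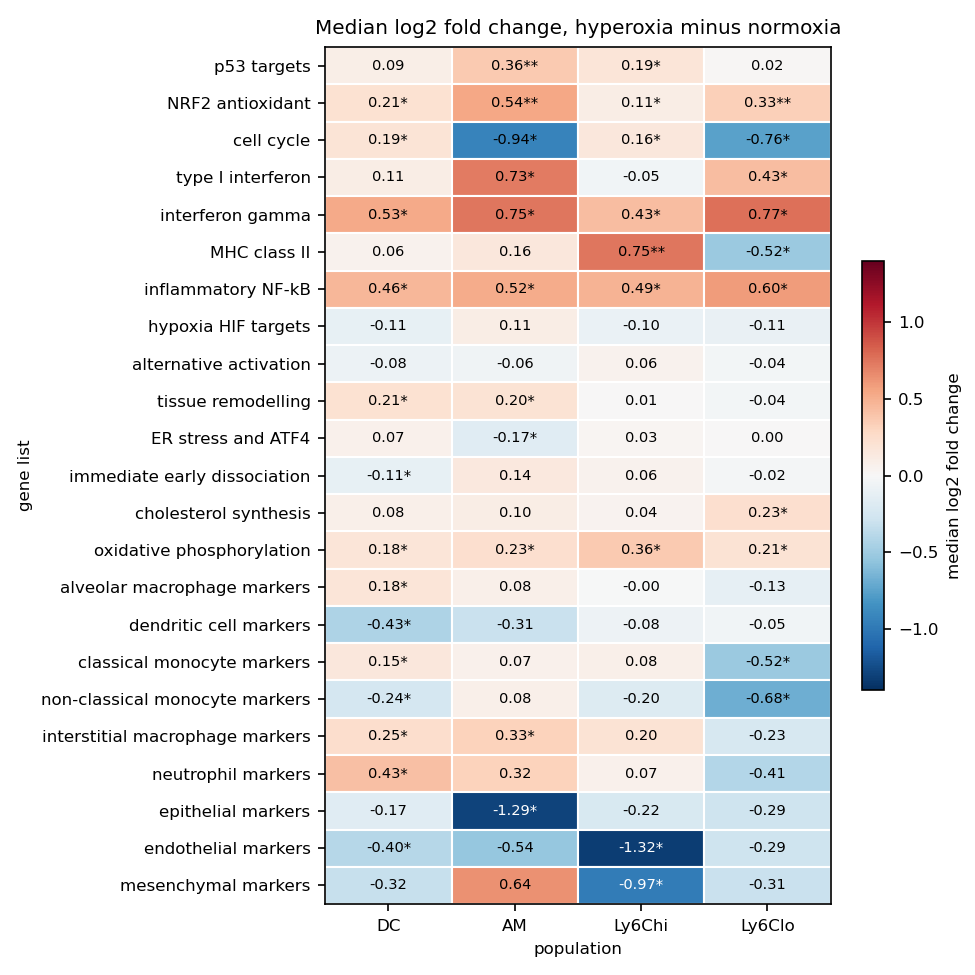
Median log2 fold change (hyperoxia minus normoxia) of the 23 gene lists with at least 4 measured genes in every population, with 1 asterisk for an adjusted p under 0.05 by camera with the preset correlation and a pair of asterisks where it also holds with an estimated correlation. The pair marks the NRF2 list in AM (0.54) and Ly6Clo (0.33), p53 targets in AM (0.36) and MHC class II in Ly6Chi (0.75).

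Across the populations 48 of 112 list tests were called with the preset correlation, 33 higher and 15 lower, 4 with an estimated correlation, 6 by fry and 16 by its mixed form. At an unadjusted p under 0.05 the camera count was 52. Metallothionein and zinc genes (smallest adjusted p = 0.0951, in AM with a median of 0.48), alternative activation (0.485), erythroid markers (0.517) and markers of granulocytes, mast cells and platelets (0.62) were called in no population. Neutrophil markers were called in DC, mesenchymal markers in Ly6Chi and T and NK cell markers in AM, and in no other population.

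The series title names interferon gamma. Its gene, Ifng, had 0 counts in every AM and Ly6Clo library and in every normoxic Ly6Chi library. In hyperoxic Ly6Chi it was at 5.33 ± 10.9 CPM, with counts in 2 of 5 libraries and up to 24.8 CPM. T and NK cell markers had a mean log2 CPM of 1.28 in hyperoxic Ly6Chi, up to 3.65, against 0.37 in normoxic Ly6Chi, and which cells carry Ifng was not tested. In DC it was at 0.307 ± 0.359 CPM in normoxia and 0.799 ± 0.754 CPM in hyperoxia, with counts in 3 of 6 and 4 of 5 libraries. These counts were too few for a test. The receptor gene Ifngr1 was at 841 ± 119 CPM in normoxic and 856 ± 191 CPM in hyperoxic Ly6Chi and at 708 ± 118 and 580.2 ± 183 CPM in Ly6Clo. Ifngr2 was at 324 ± 31.6 and 332 ± 22.0 CPM in Ly6Chi. Neither receptor gene was called under hyperoxia in any population. Since 0 genes were called in DC, Ly6Chi and Ly6Clo and 11 in AM, this says little of the receptors. The mean of the interferon gamma list was highest in hyperoxia replicate 3, of litter 100, in all 4 populations, at 8.05 in DC, 5.85 in AM, 7.39 in Ly6Chi and 7.31 in Ly6Clo on the log2 CPM scale. Hyperoxia replicate 5, of litter 108, came next in all 4, at 6.60, 5.42, 5.80 and 5.99, against at most 6.06, 4.11, 5.17 and 4.64 in normoxic libraries and 5.88, 3.47, 5.12 and 4.29 in the other 3 hyperoxic ones. Without litter 100 the median of the list was 0.12 in DC (adjusted p = 0.207), 0.30 in AM (0.0430), 0.14 in Ly6Chi (0.0520) and 0.19 in Ly6Clo (0.0146). Without litter 93 it was 0.90, 1.26, 0.74 and 1.43 in the same order.

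The 11 genes called in AM were set beside the other populations to ask how far the responses overlap. All 11 were higher in hyperoxic Ly6Clo (median log2 fold change 0.77), 10 of 10 measured in DC (0.43) and 8 of 10 in Ly6Chi (0.19), but none was called there. Blvrb had 0.92 ± 0.24 in DC, 0.82 ± 0.31 in Ly6Chi and 0.77 ± 0.20 in Ly6Clo, and Clec4d had 1.42 ± 0.61, 0.45 ± 0.31 and 1.23 ± 0.44. No gene was called in both of any pair of populations, and 0 were expected. Without the filter on low counts the 6 pairs shared 338 calls of the same sign in all. Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.44 (rho = 0.40) between AM and Ly6Clo and at r = 0.16 to 0.31 in the other 5 pairs. With unadjusted p under 0.05 in both, AM and Ly6Clo shared 182 genes of the same sign and 2 of opposite sign, where 24.6 of the same sign would be expected if independent. The counts of same and opposite sign were 73 and 32 for AM and Ly6Chi (24.8 expected) and 50 and 19 for Ly6Chi and Ly6Clo (13.6). With DC they were 117 and 18 for AM (40.8), 86 and 5 for Ly6Chi (23.7) and 72 and 13 for Ly6Clo (22.9). The comparisons share litters and may share pups, so they are not independent. The test of whether the hyperoxia effect differs between the 4 populations called 0 of 12529 genes by edgeR, with 617 at an unadjusted p under 0.05, 21 called by DESeq2, 14 by limma voom and 524 by edgeR without the filter on low counts. Without a single library it called 5 (AM hyperoxia replicate 2), 2 (AM hyperoxia replicate 1, Ly6Clo normoxia replicate 5 or Ly6Clo hyperoxia replicate 5) or 1 (Ly6Chi hyperoxia replicate 2 or AM normoxia replicate 4).

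Between Ly6Chi and Ly6Clo the hyperoxia effect on MHC class II genes differed, with a median difference (Ly6Chi minus Ly6Clo) of 1.25 and 9 of 9 positive (camera adjusted p = 1.33e-13, adjusted p = 0.00524 with an estimated correlation). Over the list alone 6 of 9 differed, against 0 over all genes, among them H2-Ab1 (1.57 ± 0.36), H2-Eb1 (1.80 ± 0.47), H2-Aa (1.99 ± 0.66) and the invariant chain Cd74 (0.80 ± 0.31). B cell markers differed in the same direction, with a median of 2.18 (2.29e-11, adjusted p = 0.0177 with an estimated correlation). Cd79a (2.32 ± 0.62), Cd79b (1.13 ± 0.36) and Ms4a1 (2.48 ± 0.83) of 6 differed over the list alone, against 0 over all genes.

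Cell cycle genes had a median difference of 0.95 (camera adjusted p = 4.80e-16, adjusted p = 0.190 with an estimated correlation). Of these, Kif11 (2.36 ± 0.63) and Cdca8 (1.43 ± 0.40) of 36 passed over the list alone and 0 over all genes. Classical monocyte markers had 0.55 (0.000432, adjusted p = 0.190 with an estimated correlation). Those of the 16 that differed when adjusted over the list alone, with 0 over all genes, included Ly6c2 (1.36 ± 0.39) and Hp (0.77 ± 0.28) upward and Vcan (−2.08 ± 0.37) downward. Non-classical monocyte markers had 0.72 (4.71e-06, adjusted p = 0.236 with an estimated correlation) and interstitial macrophage markers 0.24 (0.0339, adjusted p = 0.632 with an estimated correlation). T and NK cell markers had 2.56 (0.00196, adjusted p = 0.236 with an estimated correlation), with 1 of 5 over the list alone. This was Nkg7, a granule gene, at 0.087 CPM in normoxic and 56.6 ± 99.3 CPM in hyperoxic Ly6Chi. The T and NK cell median was 1.23 without Ly6Clo normoxia replicate 2, and the non-classical monocyte median 0.47 without Ly6Clo hyperoxia replicate 5.

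Camera called 5 lists with a negative difference, with endothelial markers (−1.10, 4.40e-05, adjusted p = 0.355 with an estimated correlation) and NRF2 genes (−0.13, 0.00217, adjusted p = 0.0597 with an estimated correlation) among them. The others were type I interferon (−0.32, 0.0282, adjusted p = 0.719 with an estimated correlation), cholesterol synthesis (−0.30, 0.0325, adjusted p = 0.355 with an estimated correlation) and alveolar macrophage markers (−0.09, 0.0463, adjusted p = 0.370 with an estimated correlation). The last 3 calls and that of interstitial macrophage markers ended without any of several single libraries, named with the other settings below. The direction for type I interferon turned without Ly6Clo hyperoxia replicate 3 (median −0.0200), and the alveolar macrophage median turned to 0.02 without Ly6Chi normoxia replicate 1. The endothelial median was −0.72 without Ly6Clo hyperoxia replicate 4, and the NRF2 median −0.08 without Ly6Clo normoxia replicate 2 or Ly6Chi hyperoxia replicate 5. In all, 12 of 28 lists were called with the preset correlation, 2 with an estimated correlation and 2 by fry. The mixed form of fry called 1, classical monocyte markers (adjusted p = 3.58e-05). For single genes edgeR called 0 of 11721, with 447 at an unadjusted p under 0.05, 4 called by DESeq2, 0 by limma voom and 205 by edgeR without the filter on low counts. The smallest p belonged to the phosphatase Dusp2 (2.19 ± 0.37, adjusted p = 0.0626), Vcan (adjusted p = 0.0626), Gpr18 (2.03 ± 0.40), the lymphotoxin gene Ltb (2.58 ± 0.54) and Nkg7 (8.79 ± 1.87). The count was 2 without Ly6Clo normoxia replicate 1 or Ly6Chi hyperoxia replicate 3, and 1 without Ly6Chi normoxia replicate 4, Ly6Clo normoxia replicate 5 or litter 100.

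In normoxia Ly6Chi (n = 6) and Ly6Clo (n = 5) differed in 3380 of 10950 genes, 1811 higher and 1569 lower in Ly6Chi. Several genes of neutrophil granules were among those with the largest positive differences. Elane, neutrophil elastase, was at least 209-fold higher in Ly6Chi (87.9 ± 29.1 CPM against 0 counts in 5 Ly6Clo libraries, a floor of 0.421 CPM). Ltf, Ngp and Camp went from 1.37, 3.65 and 1.47 CPM in Ly6Clo to 318, 518 and 179 CPM in Ly6Chi. Ly6c2 was 21.8-fold higher (4.44 ± 0.20), and Vcan was higher by 5.04 ± 0.25. Other genes with the largest positive differences were Olfm4, Mpo, Cd177, Rhou, Cebpe and Stfa3. Lower in Ly6Chi were the vitamin D receptor Vdr (26.4 CPM in Ly6Clo and 0.139 CPM in Ly6Chi, −6.81 ± 0.63), the macrophage elastase Mmp12 (254 and 2.42 CPM, −6.78 ± 0.42) and the neuropeptide gene Gal (125 and 2.56 CPM, −5.53 ± 0.32). Itgax (−4.39 ± 0.28) and Igf1 (112 and 7.99 CPM, −3.70 ± 0.35) were lower too, beside Mreg, Ccn3, Kazald1, Rnf180 and Ch25h.

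By list, all 25 type I interferon genes were higher in normoxic Ly6Chi (median 2.76), among them Usp18 (21.4 to 232 CPM, 3.43 ± 0.20), Mx1 (3.55 ± 0.27) and Ifit3 (2.82 ± 0.21), and adjusted over the list alone the count was also 25. Classical monocyte markers were higher in 14 of 16 (2.08), neutrophil markers in 14 of 16, endothelial markers in 8 of 11 and interferon gamma genes in 13 of 19. Alveolar macrophage markers were lower in 14 of 17 (−2.68, 15 over the list alone) and interstitial macrophage markers in 10 of 16 (−1.93), such as C1qc (341 to 47.6 CPM, −2.69 ± 0.24). Cell cycle genes were higher in 14 of 36 (17 over the list alone). Of 9 MHC class II genes 0 were higher and 2 lower, with 1 over the list alone, H2-DMa (−0.70 ± 0.09, adjusted p = 6.50e-05). H2-Ab1 (−0.46 ± 0.21), H2-Aa (−0.24 ± 0.46) and H2-Eb1 (0.28 ± 0.32) were not called, and of 5 B cell markers 0 were called. The direction of the last pair turned without a single library, to 0.14 for H2-Aa without Ly6Clo normoxia replicate 3 and to −0.01 for H2-Eb1 without Ly6Chi normoxia replicate 4. The count was 2252 without Ly6Clo normoxia replicate 5.

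In hyperoxia Ly6Chi and Ly6Clo (5 libraries each) differed in 3373 of 10638 genes, 1704 higher and 1669 lower in Ly6Chi. Elane was at least 253-fold, Prtn3 at least 250.5-fold, Hsh2d at least 74.4-fold and Crispld2 at least 40.5-fold higher in Ly6Chi, each with 0 counts in 5 Ly6Clo libraries (a floor of 0.430 CPM). Ngp (1.34 to 507 CPM, 8.23 ± 0.30), Ltf (7.88 ± 0.38) and Camp (7.75 ± 0.34) were higher as well. The chemokine gene Cxcl14 (36.5 CPM in Ly6Clo and 0.0843 CPM in Ly6Chi, −7.29 ± 0.65), Mmp12 (−6.56 ± 0.52), Marco (−5.65 ± 0.78), Gal (−5.51 ± 0.49) and Fabp4 (−5.17 ± 0.66) were lower. Ly6c2 was at 8.55 CPM in Ly6Clo and 523 CPM in Ly6Chi (5.76 ± 0.25).

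MHC class II genes were higher in hyperoxic Ly6Chi in 4 of 8, and 4 over the list alone (median 0.73). These were H2-Eb1 (3.92-fold, 1.97 ± 0.30, adjusted p = 0.000464), H2-Aa (37.3 to 119 CPM, 1.64 ± 0.33, adjusted p = 0.00317), H2-Ab1 (91.5 to 185 CPM, 1.08 ± 0.25, adjusted p = 0.00705) and H2-Oa (1.02 ± 0.36, adjusted p = 0.0476). B cell markers were higher in 4 of 5 (2.50, 5 over the list alone), such as Cd79a (2.67 ± 0.42), Cd79b (1.44 ± 0.29) and Ms4a1 (2.62 ± 0.72). Cell cycle genes were higher in 31 of 36 (1.97, 32 over the list alone), with Ccnb2 at 40.9 CPM in Ly6Clo and 302 CPM in Ly6Chi (2.91 ± 0.23) and Cdc20 higher by 3.38 ± 0.34. Type I interferon genes were higher in 23 of 25 (2.11), classical monocyte markers in 12 of 15 (13 over the list alone) and neutrophil markers in 14 of 15. Alveolar macrophage markers were lower in 14 of 18 (15 over the list alone) and interstitial macrophage markers in 10 of 17 (11 over the list alone), and of 22 NRF2 genes 10 were lower and 5 higher. The receptor genes Ifngr1 (0.54 ± 0.12, adjusted p = 0.00586) and Ifngr2 (0.55 ± 0.12, adjusted p = 0.00363) were higher in hyperoxic Ly6Chi. In normoxia Ifngr2 (0.58 ± 0.09, adjusted p = 0.000239) but not Ifngr1 (0.22 ± 0.10, adjusted p = 0.112) was called. Without the litter term the count was 1792, without litter 93 it was 1361 and without litter 108 it was 2108, against 1883 and 2022 without litter 93 and without litter 108 in normoxia.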

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

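The tests of depth, of B cell RNA and related markers and of litter 100 were chosen only after the results they concern were seen. The tests of RNA from the Ly6Chi and DC gates were aimed at genes and a list called in those results, so they were not chosen independently of them.

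A first pattern is the rise of NRF2 antioxidant genes and of the 11 called genes in hyperoxic AM. For the list the tables argue against a difference in depth, since its median log2 fold change was 0.533 after all AM libraries were thinned to the smallest total. Most of the 11 calls remained as well. Thinning cannot undo a limit on counts of abundant transcripts, which would favour the shallower hyperoxic AM libraries. Saturation-corrected counts left the calls of the named genes unchanged. None of the 11 calls remained without libraries under 1000000 counts or with the number of detected genes as a covariate, though their signs held. For Clec4d, Itgam and Slc11a1 the tables also argue against RNA from cells of the Ly6Chi gate, whose sort excludes high CD11c. At the 24.9% share these genes would need, the median rise of 19 monocyte and neutrophil markers was 0.10 of that needed (−0.0108 to 0.167 with single AM libraries left out). Some markers did move that way, such as Ngp (5.31 to 86.2 CPM) and Camp (2.47 to 31.7 CPM), so a small share may be present. A response of the macrophages to oxygen remains as a hypothesis. RNA from cells of the Ly6Clo gate, also high in CD11c, and a changed mix of cells in the AM gate were not tested and stay open. Interstitial macrophage markers had a mean log2 CPM of 4.73 ± 0.39 (SD) in normoxic AM, 5.28 ± 0.55 in hyperoxic AM and 7.28 ± 0.74 in normoxic Ly6Clo. Alveolar macrophage markers had 7.90 ± 0.10 in normoxic and 7.86 ± 0.23 in hyperoxic AM. All 11 genes stayed called with Y-linked expression as a covariate for sex (30 called in all). This was not run for the list, and pup differences are open and untested.

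A further pattern is the MHC class II list, higher under hyperoxia in Ly6Chi and lower in Ly6Clo, the latter with the preset correlation alone and not called without normoxia replicate 5 (median −0.34). For the rise in Ly6Chi, RNA from the DC gate would be needed at 7.95%. The median rise of 13 dendritic cell markers was 0.0177 of that needed (−0.0191 to 0.0981 with single libraries left out), which argues against it. Of the 13 only Cd24a, named after its value was seen, rose more than needed (31.8 against 20.3 CPM). Less DC RNA in Ly6Clo, for the fall and the difference, was not tested. RNA from B cells, which carry MHC class II and for which the labels name no sort marker, stays open too. Litter was not removed in the correlations that follow, so their p-values treat littermates as independent libraries. Within oxygen groups the B cell and MHC class II means of the 11 Ly6Chi libraries correlated at r = 0.749 (permutation p = 0.0101, adjusted 0.0322; rho = 0.727, permutation p = 0.0245, adjusted 0.0441; 4 relations; r = 0.703 without the 2 farthest libraries), and in Ly6Clo at r = 0.687 (permutation p = 0.0458; rho = 0.673, permutation p = 0.0549, not past the threshold), or 0.345 without the 2 farthest, but dendritic cell markers followed MHC class II too, so the relation is not particular to B cell markers (Ly6Chi r = 0.593, permutation p = 0.0348, adjusted 0.0458, rho = 0.664, or r = 0.128 without the 2 farthest; Ly6Clo r = 0.775, permutation p = 0.0161, adjusted 0.0322, rho = 0.770, or r = 0.717). With the B cell mean as a covariate the median fell from 0.75 to 0.32 in Ly6Chi and went from −0.52 to −0.13 in Ly6Clo, and the members risen over the list alone fell from 5 to 0 in Ly6Chi, but 7 of 9 were still higher there (camera p = 0.00195; 0.0504 with an estimated correlation) and the difference between the populations fell from 1.25 to 0.49 with 9 of 9 positive (0.00181; 0.0429), though B cell markers, none of which is in another list, were higher in normoxic DC in 6 of 6, and which cells carry them was not tested.

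The last pattern is the interferon gamma list, higher under hyperoxia in all 4 populations with the preset correlation but in none with an estimated one (adjusted p 0.346 to 0.408), where its mean was above every normoxic library in hyperoxia replicates 3 (litter 100) and 5 (litter 108) and in none of the other 3. A difference in depth between the oxygen groups is argued against, since the lowest ratio of the thinned to the reported median was 0.878. Hyperoxia replicate 3 was the shallowest hyperoxic library of each population (1309747 counts in DC, 551960 in AM, 1026528 in Ly6Chi and 647844 in Ly6Clo). It also had the fewest genes detected among them, and thinning cannot set its quality apart. Hyperoxia replicate 5 was not shallow (1960855, 1636916, 2298828 and 1867998 counts in the same order). Litter 100, with 1 hyperoxic library in each population, could carry most but not all of the rise: without it the highest of the 4 ratios to the reported median was 0.396, with medians of 0.12 to 0.30. Whether the high levels of hyperoxia replicates 3 and 5 come from the pup, the litter, the handling or the quality of the library cannot be settled. There is 1 such library per population in each of 2 litters, and the populations may share pups. A weaker rise remained in AM and Ly6Clo without this litter (adjusted p = 0.0430 and 0.0146; 2.58e-15 to 0.0430 and 8.99e-14 to 0.0146 without each litter or thinned).

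Other results stood out by the distance of a single library from its group, which chance gives in about 1 of 20 groups; 5 of 86 groups did so. The mean of the NRF2 list was 7.04 in AM hyperoxia replicate 4, against 6.85 to 6.88 in the other 4. The mean of the p53 list was 4.45 in AM normoxia replicate 6, against 4.75 to 4.92. The mean of the MHC class II list was 4.74 in AM hyperoxia replicate 3, against 5.88 to 6.32. Zmat3 was at 14.7 CPM in AM normoxia replicate 4, against 18.5 to 20.6 CPM. Dst was at 538 CPM in AM hyperoxia replicate 3, against 169 to 213 CPM.

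The remaining results are the 12 lists whose hyperoxia effect differed between Ly6Chi and Ly6Clo by the test of the difference itself (camera adjusted p, preset correlation). With an estimated correlation 2 of the 12 remained, MHC class II and B cell genes, and 6 of 60 splits of the oxygen labels gave at least 12 lists (highest other 16), so chance cannot be excluded for the count. The effect was more positive in Ly6Chi for cell cycle (4.80e-16), MHC class II (1.33e-13), B cell (2.29e-11), non-classical monocyte (4.71e-06), classical monocyte (0.000432), T and NK cell (0.00196) and interstitial macrophage genes (0.0339). It was more negative for endothelial (4.40e-05), NRF2 (0.00217), type I interferon (0.0282), cholesterol synthesis (0.0325) and alveolar macrophage genes (0.0463).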

How the results depend on the processing

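The fits thinned to the smallest library, corrected for saturation or without libraries under 1000000 counts, and the list tests with single libraries left out, were chosen after seeing the data. Counts stayed within 1.5 times their value under DESeq2 size factors (15 of 15), the filter at 10 CPM (12 of 12) and saturation-corrected counts (8 of 8). Leaving out the block of litters (the labels give no other pairing) gave 1792 genes between Ly6Chi and Ly6Clo in hyperoxia, and the other 14 counts held. Without the filter the hyperoxia counts were 369 in DC, 325 in AM, 235 in Ly6Chi and 173 in Ly6Clo, the differences between populations gave 524 and 205, and the overlap 338. Most were among genes that pass it (315, 274, 187, 119, 476 and 174). DESeq2 gave 24, 111, 5, 1, 21 and 4 in the same order, and limma voom 1 in DC, 258 in AM and 14 for the difference between the 4 populations. The number of detected genes as a covariate gave 0 in AM and 1583 for DC against the others, and Y-linked expression gave 30 in AM and 3 for the 4 populations. Without litter 93 the counts were 2 in DC, 0 in AM, 1 in Ly6Chi, 1883 and 1361 between Ly6Chi and Ly6Clo in normoxia and hyperoxia, and 2562 and 861 for DC and Ly6Clo against the others. Without litter 108 they were 5 in AM, 2022, 2108 and 922 (Ly6Clo against the others), and without litter 100 it was 1 for the difference between Ly6Chi and Ly6Clo. All 43 libraries together gave 27 in AM, 1 in Ly6Chi and 3 in Ly6Clo, thinning gave 18 in AM (10 shared with the 11), and leaving out small libraries gave 0 in AM, where fewer libraries were left. With an estimated correlation 4 lists and 2 lists remained. Apart from fits with fewer libraries, the cause was not tested.

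With 1 library left out counts ranged from 0 to 23 in DC, 5 to 39 in AM, 0 to 0 in Ly6Chi, 0 to 1 in Ly6Clo, 0 to 5 for the 4 populations, 0 to 2 for Ly6Chi against Ly6Clo effects, and 2252 to 3638 between Ly6Chi and Ly6Clo in normoxia. Values that changed sign were not called, except lists called with the preset correlation. These were Pecam1 in AM (0.12, detected genes), Mt1 (−0.00585), Lgals3 (−0.0780), Cox7a2 (−0.0241), Ndufb9 (−0.0158) and Ndufa2 (−0.00221) in AM without small libraries, and Ifi205 in Ly6Clo (−0.0203 without small libraries; −0.0203 to 2.43 over single libraries left out). In the difference between Ly6Chi and Ly6Clo, Rsad2 went to 0.34 by limma voom and Lcn2 to 0.23 without litter 108. With single libraries left out, H2-Aa ranged from −0.52 to 0.14 (without Ly6Clo normoxia replicate 3) and H2-Eb1 from −0.00771 (without Ly6Chi normoxia replicate 4) to 0.48 between Ly6Chi and Ly6Clo in normoxia. List medians went to −0.47 for neutrophil markers in DC (without litter 93), −0.17 for type I interferon in Ly6Clo (without litter 100; −0.14 without small libraries, and −0.14 to 0.53 over single libraries left out), −0.0190 for cell cycle in DC (without litter 108) and −0.11 for oxidative phosphorylation in AM (without small libraries). The test's direction for type I interferon in Ly6Chi against Ly6Clo turned at a median of −0.0200 without Ly6Clo hyperoxia replicate 3, which is the small library there, and over single libraries left out the median ranged from −0.48 to −0.0200. The cause was not tested. Depth limits genes with low counts, and the self-test shows that many 2-fold changes would be missed.

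List calls (preset correlation) that ended with 1 library left out follow, with the adjusted p without it. In DC they ended without hyperoxia replicate 3 for non-classical monocyte and classical monocyte (each 0.177), endothelial (0.128), interstitial macrophage (0.123), immediate early (0.348), interferon gamma (0.155), NF-kB (0.806) and tissue remodelling genes (0.0741). Others in DC ended without hyperoxia 1, 2 or 4 or normoxia 1, 2 or 6 for alveolar macrophage markers (0.0652 to 0.237), hyperoxia 1, 4 or 5 or normoxia 5 for cell cycle (0.0515 to 0.541), and hyperoxia 1 or 2 or normoxia 2 or 5 for neutrophil markers (0.0713 to 0.24, with a median of −0.09 without normoxia 2). They also ended without normoxia 3 or 4 for immediate early (0.0506 and 0.0637), normoxia 4 or 6 for classical monocyte (0.0581 and 0.0555), normoxia 1 or 3 for interstitial macrophage (0.133 and 0.0519), normoxia 5 or hyperoxia 5 for endothelial (0.117 and 0.204), hyperoxia 5 for non-classical monocyte markers (0.0773) and normoxia 3 for NF-kB genes (0.0536). In AM they ended without normoxia 1 for oxidative phosphorylation and ER stress (each 0.0503), hyperoxia 4 for ER stress (0.121) and interstitial macrophage markers (0.0821), hyperoxia 1 for the latter (0.0527) and tissue remodelling (0.121), normoxia 2 for tissue remodelling (0.111), and hyperoxia 1, 2, 3, 4 or 5 or normoxia 3, 4 or 6 for T and NK cell markers, of which 1 to 3 were tested (0.0507 to 0.208, with a median of −0.06 without hyperoxia 4). In Ly6Chi they ended without normoxia 1, 3 or 6 or hyperoxia 2 or 3 for NRF2 (0.0554 to 0.142), normoxia 1 or 5 or hyperoxia 1 for cell cycle (0.0689 to 0.183), normoxia 2, 3, 5 or 6 or hyperoxia 1, 4 or 5 for p53 (0.0542 to 0.18), hyperoxia 2 or 5 for mesenchymal (0.0608 and 0.0589) and hyperoxia 3 for interferon gamma genes (0.0567). In Ly6Clo they ended without normoxia 5 for MHC class II (0.0603) and cholesterol synthesis (0.335), normoxia 1 or 5 or hyperoxia 5 for classical monocyte (0.0688 to 0.485), hyperoxia 2 or 3 for oxidative phosphorylation (0.0511 and 0.938) and normoxia 3 or 4 or hyperoxia 3 for type I interferon genes (0.0669 to 0.17, with a median of −0.14 without hyperoxia 3). In the difference between Ly6Chi and Ly6Clo the call of cholesterol synthesis ended without Ly6Chi normoxia 1 or 4 or hyperoxia 2, 4 or 5 or Ly6Clo normoxia 3 or 4 or hyperoxia 4 or 5 (0.0536 to 0.159). That of alveolar macrophage markers ended without Ly6Chi normoxia 1, 3, 4 or 6 or hyperoxia 2, 3, 4 or 5 or Ly6Clo normoxia 1, 2, 3 or 4 or hyperoxia 1, 2, 3 or 4 (0.0539 to 0.189, with a median of 0.02 without Ly6Chi normoxia 1). That of interstitial macrophage markers ended without Ly6Chi normoxia 1 or 2 or hyperoxia 4 or 5 or Ly6Clo normoxia 1, 2 or 3 or hyperoxia 3 or 5 (0.0591 to 0.427). That of type I interferon genes ended without Ly6Chi normoxia 2 or 5 or hyperoxia 5 or Ly6Clo normoxia 3 or 4 or hyperoxia 3 or 5 (0.0576 to 0.462, with the test's direction changed without Ly6Clo hyperoxia 3), and the other 8 calls held in these fits.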

Other observations

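The splits without the filter on low counts were chosen after their counts were seen. The other tests in this part were planned, and the named genes follow the rule.

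In normoxic AM, where 6059 of 11979 genes differed, 17 of 28 oxidative phosphorylation genes and 19 of 36 cell cycle genes were higher than in the mean of the other populations, and 15 of 18 immediate early genes (16 over the list alone) and 6 of 6 B cell markers were lower. DC were higher in 20 of 26 type I interferon and 16 of 22 interferon gamma genes. Ly6Clo were higher in 9 of 15 non-classical monocyte markers (14 over the list alone) and in 10 of 20 tissue remodelling genes (11 over the list alone). Between the Ly6C populations in normoxia, Ly6Chi were higher in 11 (12 over the list alone) and lower in 3 of 18 immediate early genes, lower in 8 of 18 ER stress and ATF4 genes (9 over the list alone), and higher in the matrix gene Thbs1 (97.5 to 773 CPM, log2 fold change 3.08 ± 0.18).

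Other splits of the same libraries into groups of the same sizes show how far chance can be excluded. For the 11 genes in AM the highest other of 100 splits had 6, and 1 split, the real one, had as many as 11. Splits were drawn across litters, so most set the labels less evenly against litter than the real one does. The count of 11 alone thus does not exclude chance. At an unadjusted p under 0.05, 6 of 100 splits reached the 990 genes in AM (highest other 1251). Chance can be excluded for the 3380 and 3373 genes between Ly6Chi and Ly6Clo (highest others 1603 and 46). The same holds for the 4049, 6059 and 5220 genes of DC, AM and Ly6Chi against the others (0, 2263 and 493 in 60 splits). For the 1440 genes of Ly6Clo against the others the highest other of 60 splits had 1062. At an unadjusted p under 0.05, 2 of 60 splits, the real one included, reached its 2869 genes (highest other 3533). For the 48 lists with the preset correlation (highest other 43, median of the others 27) and the 4 and 2 lists with an estimated correlation (highest other 1 each), 1 split, the real one, gave as many. Each population was split separately, which may understate the spread where populations share pups, so this alone does not exclude chance. Chance cannot be excluded for the 12 lists of the difference between Ly6Chi and Ly6Clo, which 6 of 60 splits reached (highest other 16). For the counts of 0 the splits decide nothing, since any split gives at least 0 (100 of 100 in DC, Ly6Chi and Ly6Clo, 40 of 40 for the 4 populations and 60 of 60 for Ly6Chi against Ly6Clo effects, with highest others of 204, 1223, 1036, 4 and 2). The splits with 204, 1223 and 1036 genes call many more than the real ones. They put all libraries of litter 108 (DC) or litter 93 (Ly6Chi and Ly6Clo) together with hyperoxia replicate 3, and the other of these litters wholly in the opposite group. With litter in the fit, only litter 100 then sets the contrast, and its labels are the real ones. These counts thus set hyperoxia replicate 3 against the normoxic libraries of litter 100 and say little of chance.

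Without the filter on low counts edgeR called many genes in other splits too. Of 100 splits, 8 gave at least the real 369 genes in DC, 6 the 235 in Ly6Chi and 31 the 173 in Ly6Clo, so chance cannot be excluded for these (highest others 774, 941 and 992, medians of the others 63, 35 and 98). The same holds for the 524 genes of the 4 populations (17 of 40 splits, highest other 921) and the 205 of Ly6Chi against Ly6Clo effects (20 of 60, highest other 436). In AM 3 of 100 splits, the real one included, gave at least the real 325 (highest other 405, median of the others 66), a share under 0.05, though 97 of the 99 others called genes.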
